A study of Mus musculus with 20 samples.

How the data were processed

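Polyadenylated RNA from the mouse bed nucleus of the stria terminalis was sequenced in 20 libraries, 5 from each of 4 groups: female controls, male controls, susceptible females and susceptible males. Per the labels' protocols, total RNA was extracted with Trizol, cDNA libraries were made from polyadenylated RNA, and paired reads were sequenced on an Illumina HiSeq instrument. The authors deposited 1 table of read counts per gene for each library, and whole numbers with unequal sums per library show that the deposited counts are not normalized. The submitters' processing notes name HISAT2, a spliced aligner, featureCounts, which counts reads per gene, and the mm10 mouse assembly. Their versions, the annotation, the strand setting and the handling of reads with several matches are not given in the sources used here, so reads that overlapping, antisense or near-identical genes share cannot be separated. Groups came from the sample titles, which also give the replicate numbers, and sex stands in the labels under genotype.

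The tables list 19214 genes. Of these, 19206 were matched by identifier to GENCODE release 21 on GRCm38, which gave symbols, positions, GC content and exon length, and the 8 unmatched genes held 0.0026% of the counts. The tables are close to a protein-coding set (99.8% of genes), so noncoding transcripts were hardly covered, and 265 genes had 0 counts in all libraries. Total counts of 14637636 to 17862840 per library set the precision, and floors for genes with 0 counts (3 counts over the group) cover counting error only, since the reads carry no molecular identifiers. No pair of libraries in a group agreed within sampling noise, by a chi-square test of counts over genes, so none was treated as a repeat.

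The design, the tests, the gene lists, the naming rule and a first set of alternatives were fixed before the data were examined. Counts were scaled by TMM and filtered with filterByExpr, which left 14884 genes, and were fitted over all 20 libraries with 1 mean per group by the robust quasi-likelihood method of edgeR 4.0.16 under R 4.3.3. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic. The contrasts were susceptible against control in each sex, their mean, their difference (female minus male), and male against female in control and in susceptible mice. Gene lists with at least 5 tested members, 37 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with the correlation estimated per list and with fry. The lists covered stress signalling, peptides and receptors, transmission, glial, vascular and blood cells, neighbouring brain regions, housekeeping processes and X-linked escape genes. List scores per library were compared by exact 2-sided permutation tests, whose smallest possible p with 5 against 5 libraries is 0.00794.

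Genes were named by rule in each comparison. The rule took, among called genes with a mean of at least 1 CPM whose sign held without each library in turn and leaving out predicted models, the 8 largest changes in each direction, then up to 4 passing members of each gene list with the smallest adjusted p. It also took 25 stress, peptide and steroid genes in both stress comparisons whatever their result, and, where fewer than 5 genes passed, the 5 smallest p-values in each direction. Members of gene lists given as examples beside a list's result were picked after their values were seen, as were Ttr, Pmch, Oxt and Slc17a7, Lars2 per library, and Uba1y.

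The code was tested on simulated data before use. Counts for the 14884 genes were drawn from the real means, spreads and library sizes with 200 genes changed by known folds. With edgeR, between 50% and 69% of genes changed 1.5-fold and between 78% and 89% of those changed 2-fold were recovered in the 5 group contrasts, with 3 to 7 false calls, and 34% and 65% with 4 false calls for the difference between sexes. DESeq2 made 13 to 27 false calls in the same data and limma voom with quality weights 3 to 5. Genes were drawn independently, so variation that many genes share between libraries was absent. The real libraries hold such variation, so these rates may be too favourable for them.

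The alternatives fixed at the start were DESeq2 size factors in the edgeR fit, the DESeq2 1.42.0 Wald test, no count filter, a filter of at least 1 CPM in at least 5 libraries, the replicate number as a block, 1 surrogate variable from sva 3.50.0, limma voom with sample quality weights, a fit of the 2 groups alone, and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out libraries with over 100 CPM of Ttr or over 1 CPM of Pmch, the region score (mean log2 CPM of the striatal list minus that of the thalamic list) as a covariate, offsets from a smooth trend on GC content and exon length (mgcv 1.9.3), and quality weights together with either the GC and length trend removed or the region score. Xist and Tsix were not analysed here, and a few genes that the naming rule or a list took are not reported here. No sample was left out of the main results.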

Results

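RNA was sequenced from the bed nucleus of the stria terminalis (BNST), a small forebrain region that connects the amygdala with the hypothalamus and the brain stem, of female and male mice. In each sex, mice of an anxiety model made by chronic restraint stress, in which an animal is repeatedly held in a confined space, were set beside control mice. The labels call the stressed mice susceptible and do not say how susceptibility was decided. Each of the 4 groups (female controls, male controls, susceptible females and susceptible males) held 5 libraries, 20 in all. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Total counts per library ranged from 15045809 to 17225841 in female controls and from 14758273 to 17862840 in male controls. They ranged from 14863126 to 17621275 in susceptible females and from 14637636 to 16120613 in susceptible males. Unless stated otherwise, expression is given as mean CPM ± SD over 5 libraries, where CPM are counts scaled to library size, and changes as log2 fold change ± standard error. Gene positions refer to the GRCm38 (mm10) assembly.

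The sex labels were checked first against Y-linked genes. Uty, Kdm5d and Eif2s3y, broadly expressed genes of the Y chromosome, had 0 counts in all 10 female libraries. In the 10 male libraries they reached 22.3 ± 2.04, 49.8 ± 4.33 and 57.8 ± 6.2 CPM (SD, n = 10), at least 1201-fold, 2684-fold and 3118-fold higher than a floor of 3 counts over the female libraries together. Ddx3y, a Y-linked RNA helicase gene, had 3 counts in all female libraries together and 1097 to 1849 counts in each male library. The inactivation transcript Xist and its antisense partner were not analysed here.

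Libraries of 1 group differed widely in the RNA of structures that lie next to the BNST. Ttr, the transthyretin gene of the choroid plexus, ranged from 6.96 CPM in male control 1 to 2001 CPM in susceptible female 3 and exceeded 100 CPM in 7 libraries. Pmch, a peptide gene of the lateral hypothalamus, was 118 CPM in female control 1, 23.6 in female control 2 and 11.2 in female control 3. It was 8.35 CPM in susceptible female 4, 23.5 in susceptible male 5 and under 1 CPM in the other libraries, so that 3 of 5 female controls and 0 of 5 male controls exceeded 1 CPM. Oxt, the oxytocin gene, ranged from 0.230 to 177 CPM, and Slc17a7, a glutamate transporter gene of cortex and hippocampus, from 11.1 to 719 CPM. The first principal component held 34.3% of the variance between libraries. A region score, the mean log2 CPM of striatal markers minus that of thalamic markers, was -1.28 ± 1.94 in female controls, 0.84 ± 0.83 in male controls, 0.21 ± 1.73 in susceptible females and 0.22 ± 1.57 in susceptible males. Its largest difference between compared groups, 2.12 between male and female controls, had an exact 2-sided permutation p of 0.0714 (n = 5 and 5; adjusted p = 0.324 over 68 tests of list scores).

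**Figure D1:**
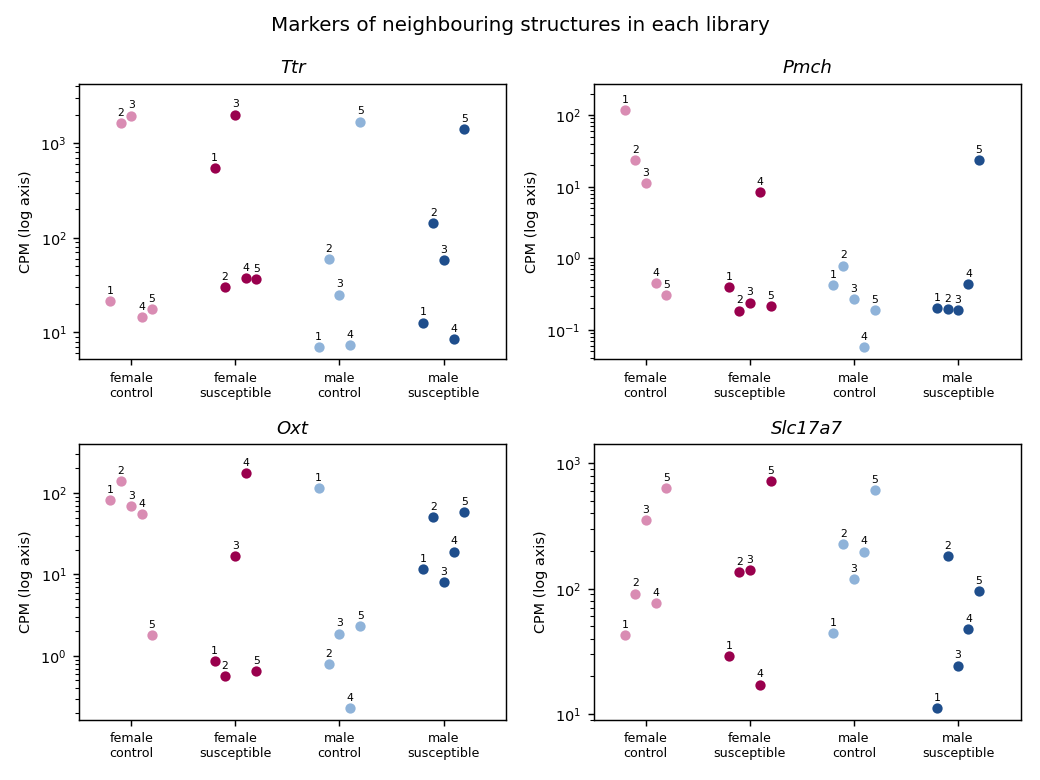
CPM of Ttr, Pmch, Oxt and Slc17a7 on log axes in each of the 20 libraries, by group, with points numbered by replicate. Ttr spanned 6.96 to 2001 CPM, and libraries of 1 group lay far apart for all 4 genes.

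Female mice after stress were compared with female controls to find transcripts that differ with chronic restraint. Sgk1, a kinase gene induced by glucocorticoids, was 95.6 ± 11.1 CPM in controls and 133 ± 18.3 CPM in susceptible females (log2 fold change 0.48 ± 0.13; chromosome 10, 21882184 to 21999903), with no overlap between the groups. All 25 striatal neuron markers stood higher in susceptible females (median log2 fold change 0.81) and all 26 oligodendrocyte and myelin markers lower (median -0.31). No single gene passed the test over all 14884 genes (edgeR quasi-likelihood, smallest adjusted p = 0.774). At an unadjusted p under 0.05 there were 871 genes, with 744 expected by chance, and DESeq2 and limma voom with quality weights also called 0 genes. Leaving out susceptible female 4 gave 2 calls, Nyap1 and Sstr1, both lower with stress and the latter named after its values were seen. In simulated libraries of this comparison, with genes drawn independently, edgeR recovered 52% of genes changed 1.5-fold and 78% of those changed 2-fold.

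The genes with the smallest p-values in females, none of which passed, were Zfp536 (-0.42 ± 0.09), a zinc finger repressor, 4933402D24Rik (-0.90 ± 0.22), Tmem200c (-0.46 ± 0.12), Nyap1 (-0.27 ± 0.07) and Lars2 (-1.11 ± 0.29) on the lower side. On the higher side they were Taf1d (0.31 ± 0.07), a subunit of the RNA polymerase I initiation factor, Bbip1 (0.34 ± 0.08), a component of the ciliary BBSome, the ephrin receptor gene Epha2 (0.89 ± 0.23), Cd302 (0.53 ± 0.14) and the ubiquitin ligase gene Rnf103 (0.22 ± 0.06), all at an edgeR adjusted p of 0.774. Lars2, the mitochondrial leucyl-tRNA synthetase, was 257 ± 120 CPM in female controls and 119 ± 16.4 CPM in susceptible females. Its levels in female controls 1, 2 and 3, which were also the female controls with more than 1 CPM of Pmch, were 376, 388 and 231 CPM.

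Among the 25 stress, peptide and steroid genes that were to be named whatever their result, Sgk1 alone passed in females when adjusted over the list alone (edgeR adjusted p = 0.0447), against 0 of 25 over all genes tested. The opioid and tachykinin precursors Penk (0.83 ± 0.46, from 347 ± 210 to 617 ± 268 CPM), Pdyn (0.52 ± 0.43) and Tac1 (0.73 ± 0.43) had positive estimates, as had neurotensin Nts (0.46 ± 0.39), the immediate early gene Fos (0.28 ± 0.24) and the corticotropin-releasing hormone gene Crh (0.29 ± 0.28, 6.08 ± 2.07 and 7.4 ± 3.56 CPM). Estimates were negative for the PACAP precursor Adcyap1 (-0.77 ± 0.61), its receptor Adcyap1r1 (-0.13 ± 0.10), the neurotrophin Bdnf (-0.43 ± 0.40), the oxytocin receptor Oxtr (-0.29 ± 0.20), the estrogen receptor Esr1 (-0.29 ± 0.45), aromatase Cyp19a1 (-0.91 ± 0.61), the CRH binding protein Crhbp (-0.21 ± 0.34) and the CRH receptor Crhr1 (-0.14 ± 0.13). Of these, the estimates of Esr1 and Crhbp lay within 1 standard error of 0. The remaining genes reported also lay within 1 standard error of 0: the glucocorticoid receptor Nr3c1 (-0.08 ± 0.09), its co-chaperone Fkbp5 (0.12 ± 0.28), Crhr2 (0.11 ± 0.31), Npy (0.19 ± 0.28), Cartpt (0.15 ± 0.45), Sst (-0.03 ± 0.13), the protein kinase gene Prkcd (-0.10 ± 0.65), Tac2 (0.05 ± 0.60) and the melanocortin receptor Mc4r (0.02 ± 0.31). The list-alone call of Sgk1 in females was lost in 16 of 32 alternative settings, while its log2 fold change ranged from 0.27 to 0.55 over all 32. Adjusted over the list alone, its edgeR adjusted p was 0.0684, 0.189, 0.0741 and 0.116 without female controls 2, 3, 4 and 5, and 0.144 and 0.182 without susceptible females 1 and 3. Through the shared spread it was 0.0571, 0.0549 and 0.0531 without male controls 1, 3 and 5, and 0.052, 0.0581 and 0.0595 without susceptible males 2, 3 and 4. It was 0.989 without the libraries over 100 CPM of Ttr, 0.224 without those over 1 CPM of Pmch and 0.0943 with the replicate block, and limma voom with quality weights gave 0.0562.

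**Figure D2:**
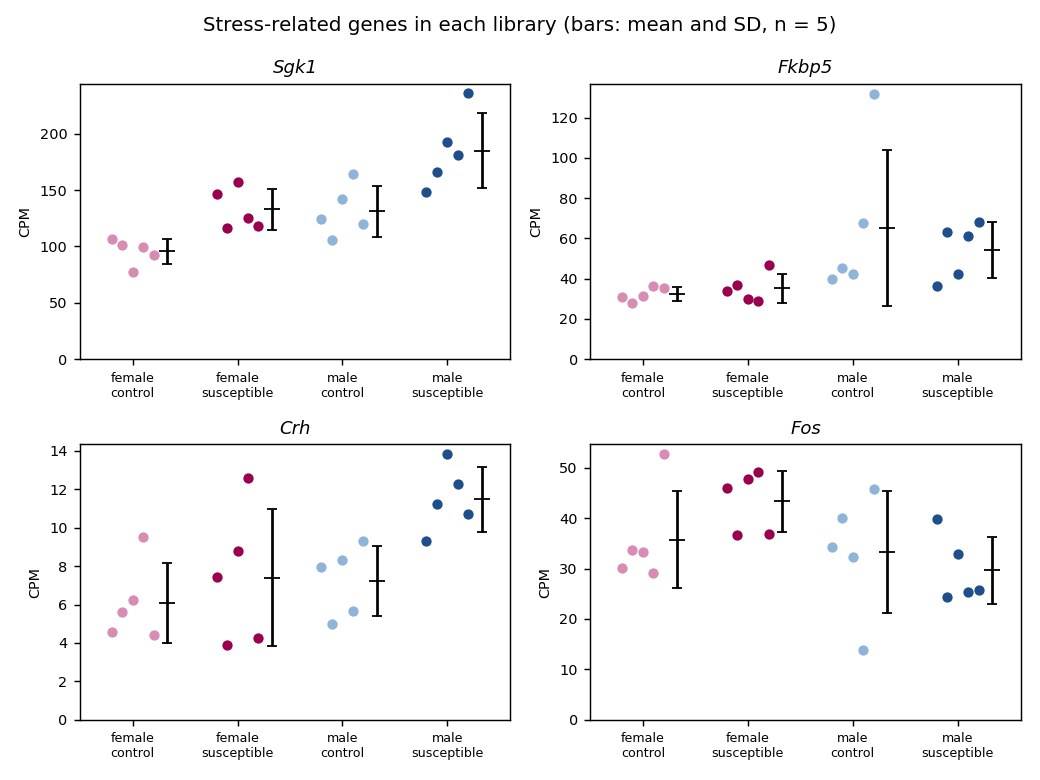
CPM of Sgk1, Fkbp5, Crh and Fos in each library by group, with the mean and SD of 5 libraries. Sgk1 averaged 95.6 and 133 CPM in control and susceptible females and 131 and 185 CPM in control and susceptible males.

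By group, 16 of 37 gene lists stood apart from other genes in females when limma camera used a preset correlation of 0.01, 7 higher and 9 lower, and none when the correlation was estimated (smallest adjusted p = 0.411 with an estimated correlation). With the preset correlation, other splits of the same libraries called a median of 11 lists in females, 10 in males, 10 for the difference between the sexes and 11 between controls. A call with the preset correlation alone therefore does not show an effect of the groups. Striatal markers, which mark the medium spiny neurons beside the BNST, were higher in 25 of 25 members (camera adjusted p = 5.29e-11, and 0.411 with an estimated correlation), among them the dopamine receptor genes Drd2 (0.88 ± 0.39) and Drd1 (0.99 ± 0.50). The region score, built in part from these markers, was 1.48 higher in susceptible females (exact permutation p = 0.23, n = 5 and 5). Myelin markers were lower in 26 of 26 members (camera adjusted p = 1.25e-08, and 0.422 with an estimated correlation), with Mobp at -0.32 ± 0.14 and Mbp at -0.32 ± 0.15. Astrocyte markers were lower in 17 of 20 members (7.15e-05, and 0.411 with an estimated correlation), among them the intermediate filament gene Gfap (-0.59 ± 0.19) and the water channel gene Aqp4 (-0.29 ± 0.12). Cholesterol synthesis genes were lower in 23 of 24 members (6.31e-06, and 0.411 with an estimated correlation). Without the libraries with over 1 CPM of Pmch, which left 2 female controls and 4 susceptible females, camera no longer called the myelin (adjusted p = 0.758), astrocyte (0.142) and cholesterol (0.0799) lists.

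Immediate early genes, which respond quickly to neuronal activity, were higher in 28 of 32 members in susceptible females (median 0.33, camera adjusted p = 1.81e-05, and 0.449 with an estimated correlation), with Fosb at 0.96 ± 0.39 and Egr1 at 0.77 ± 0.38. The score of this list per library did not separate the female groups (exact permutation p = 0.246, n = 5 and 5). All 13 mitochondrially encoded genes were higher (median 0.40, camera adjusted p = 2.78e-08, and 0.411 with an estimated correlation), and 7 of them passed when adjusted over the list alone against 0 over all genes. Mitochondrial transcripts took 5.16% of counts in female controls and 6.39% in susceptible females (exact permutation p = 0.0556, n = 5 and 5), while in males they took 5.01% in both groups. Circadian clock genes were higher in 16 of 18 members (median 0.16, camera adjusted p = 0.00381, and 0.411 with an estimated correlation). These 7 lists kept their camera calls whichever library of the female groups was left out, and the other 9 lost them without at least 1 library. Without susceptible female 1, 10 lists were called.

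In males, susceptible mice were compared with male controls in the same way. Crh was 7.24 ± 1.83 CPM in controls and 11.5 ± 1.70 CPM in susceptible males (log2 fold change 0.67 ± 0.28; chromosome 3, 19693401 to 19695396). The groups did not overlap for Crh, but only narrowly, with 9.29 CPM in male control 5 and 9.32 CPM in susceptible male 1. Sgk1 was 131 ± 22.7 and 185 ± 33.3 CPM (0.49 ± 0.13). Myelin markers stood higher in 25 of 26 members (median 0.28). Most meningeal, vascular, immediate early and circadian genes stood lower, but camera with an estimated correlation called 0 lists in males (smallest adjusted p = 0.438). None of these genes passed over all 14884 genes (edgeR quasi-likelihood, 0 calls, smallest adjusted p = 0.405; adjusted p = 0.465 for Crh). There were 1439 genes at an unadjusted p under 0.05, with 744 expected. DESeq2 called 24 genes and limma voom with quality weights 671, of which 0 passed once the trend on GC content and exon length was removed. The median absolute log2 fold change of these 671 genes was then 0.18 against 0.30 before. In simulated libraries of this comparison, with genes drawn independently, edgeR recovered 63% of genes changed 1.5-fold and 84% of those changed 2-fold.

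The genes with the smallest p-values in males, none of which passed in edgeR, were higher for Ube2v2 (0.45 ± 0.09), a ubiquitin-conjugating enzyme variant, Ndufaf2 (0.45 ± 0.10), an assembly factor of respiratory complex I, cyclin C, Ccnc (0.34 ± 0.08), Spryd7 (0.36 ± 0.08) and Cept1 (0.34 ± 0.08), a phospholipid synthesis gene. They were lower for Pcnx3 (-0.26 ± 0.05), the secreted signalling gene Wnt16 (-1.65 ± 0.36, 1.15 ± 0.417 and 0.358 ± 0.219 CPM), Map3k1 (-0.36 ± 0.08), Zswim8 (-0.20 ± 0.05) and the integrator subunit gene Ints11 (-0.28 ± 0.07), all at an edgeR adjusted p of 0.405. Pcnx3, Spryd7 and Zswim8 were among the 24 genes that DESeq2 called, and limma voom with quality weights called all 10.

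Of the 25 genes always named, Sgk1 alone passed in males when adjusted over the list alone (edgeR adjusted p = 0.0322), against 0 of 25 over all genes tested, and it did so in 25 of 34 alternative settings. Its log2 fold change lay between 0.38 and 0.60 in all of them. Its edgeR adjusted p over the list alone was 0.117 and 0.107 without male controls 2 and 5, and 0.0819, 0.0585 and 0.15 without susceptible males 3, 4 and 5. It was 0.347 without the libraries over 100 CPM of Ttr, 0.152 without those over 1 CPM of Pmch, 0.0596 with the replicate block and 0.0603 with 1 surrogate variable. Over all genes, limma voom with quality weights called Sgk1 (0.51) and Crh (0.84) in males (adjusted p = 0.0266 and 0.0312). With the GC and length trend removed as well they stood at 0.54 and 0.86, with adjusted p-values of 0.088 and 0.09. After Sgk1 and Crh, the reported estimates more than 1 standard error above 0 were those of Nts (0.60 ± 0.39), Esr1 (0.69 ± 0.46), Tac2 (0.88 ± 0.60) and Prkcd (0.67 ± 0.65), the last resting on susceptible male 5 with 350 CPM. Estimates more than 1 standard error below 0 were those of Crhbp (-0.59 ± 0.34), Sst (-0.20 ± 0.13), Tac1 (-0.55 ± 0.42) and Cartpt (-0.54 ± 0.45). Fkbp5 (-0.27 ± 0.27) was 65.2 ± 38.7 CPM in male controls, with 132 CPM in male control 5, and 54.2 ± 13.9 CPM in susceptible males. The remaining genes reported were Adcyap1 (0.58 ± 0.64), Npy (-0.25 ± 0.28), Mc4r (0.24 ± 0.30), Crhr2 (0.25 ± 0.32), Pdyn (-0.33 ± 0.43), Fos (-0.17 ± 0.24), Penk (-0.18 ± 0.46), Crhr1 (-0.04 ± 0.13), Bdnf (0.11 ± 0.41), Adcyap1r1 (0.02 ± 0.10), Cyp19a1 (0.08 ± 0.57), Nr3c1 (0.00 ± 0.09) and Oxtr (0.00 ± 0.20).

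In males, 15 of 37 lists were called by camera with the preset correlation, 7 higher and 8 lower, and 0 with an estimated correlation (smallest adjusted p = 0.438 with an estimated correlation). Myelin markers were higher (adjusted p = 4.06e-08, and 0.582 with an estimated correlation), with the cytoskeletal gene Ermn at 0.56 ± 0.18, and precursors of oligodendrocytes showed higher markers in 11 of 14 members (camera adjusted p = 0.00673, and 0.582 with an estimated correlation). GABA signalling genes were higher in 21 of 25 members (camera adjusted p = 0.00114, and 0.438 with an estimated correlation). Meningeal and fibroblast markers were lower in 16 of 18 members (median -0.46, camera adjusted p = 6.84e-06, and 0.582 with an estimated correlation), with the collagen gene Col1a2 at -0.42 ± 0.15. Endothelial and pericyte markers were lower in 22 of 25 members (camera adjusted p = 0.00114, and 0.582 with an estimated correlation), and 3 passed when adjusted over the list alone. Members included von Willebrand factor, Vwf (-0.92 ± 0.24), and claudin 5, Cldn5 (-0.52 ± 0.15).

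Immediate early genes were lower in 31 of 32 members in susceptible males (median -0.32, camera adjusted p = 0.000474, and 0.582 with an estimated correlation), with Btg2 at -0.60 ± 0.26, and circadian genes in 15 of 18 (median -0.28, camera adjusted p = 0.00053, and 0.582 with an estimated correlation), with Cry2 at -0.32 ± 0.10 and Per3 at -0.35 ± 0.11. The immediate early score had an exact permutation p of 0.0238 between the male groups (adjusted p = 0.315 over 68 tests of list scores). Interferon and antigen presentation genes were lower in 22 of 27 members (camera adjusted p = 0.00188) and inflammatory genes in 15 of 19 (0.0244), both at an adjusted p of 0.582 with an estimated correlation. The class I antigen genes H2-D1 (-0.34 ± 0.12) and H2-K1 (-0.35 ± 0.13) were among them. Heat shock and unfolded protein response genes were higher in 26 of 34 members (camera adjusted p = 0.00188, and 0.582 with an estimated correlation). These 10 lists kept their camera calls whichever library of the male groups was left out, and the other 5 did not. Without the libraries with over 100 CPM of Ttr, the immediate early (camera adjusted p = 0.0508) and heat shock (0.702) lists were no longer called.

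Averaged over both sexes, the effect of stress on single genes was largest relative to its error for Sgk1 (log2 fold change 0.49 ± 0.09). Sgk1 was higher in susceptible than in control mice of each sex by nearly the same amount. Over all genes it did not pass in edgeR (adjusted p = 0.576, 0 genes called, 1147 at an unadjusted p under 0.05 with 744 expected), and it passed when adjusted over the 25 always-named genes alone (edgeR adjusted p = 0.00115) and in DESeq2 over all genes (adjusted p = 0.00201, 29 genes called). limma voom with quality weights called 0 genes. Without the libraries with over 100 CPM of Ttr, the list-alone call of Sgk1 was lost (edgeR adjusted p = 0.152) at a log2 fold change of 0.32 (0.27 in females and 0.38 in males). Meningeal markers were lower in 18 of 18 members (median -0.48, camera adjusted p = 3.36e-08, and 0.659 with an estimated correlation), and 6 passed when adjusted over the list alone. Camera called this list whichever of the 20 libraries was left out. In females alone the call (camera adjusted p = 0.00308) was lost without female control 3 (0.0756). It was also lost there without the libraries over 100 CPM of Ttr (0.799) or over 1 CPM of Pmch (0.357). In males it was kept in both of these settings (1.63e-09 and 8.53e-10). Female controls 2 and 3, both over 100 CPM of Ttr, scored highest among female controls (0.687 and 0.756). The list score did not separate the groups in females (exact permutation p = 0.23) or in males (0.0873).

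Whether stress acted differently in the sexes was tested by the difference between the female and the male effect. The myelin markers moved in opposite directions, lower with stress in females and higher in males, with a median difference of -0.62 over 26 members (camera adjusted p = 1.45e-14, and 0.378 with an estimated correlation). The myelin score averaged 0.33 in female and -0.33 in male controls, but 0.01 and 0.00 in susceptible females and males. The opposite movement thus lay mostly in the difference between controls. The score's change with stress had an exact permutation p of 0.127 in females and 0.103 in males (n = 5 per group). Striatal markers (median difference 1.19, camera adjusted p = 2.99e-10), immediate early genes (0.70, adjusted p = 4.02e-08) and circadian genes (0.35, adjusted p = 5.92e-06) differed the other way from the myelin markers, each at an adjusted p of 0.378 with an estimated correlation. The region score, built in part from the striatal list, moved by 1.48 in females and -0.62 in males (exact permutation p = 0.23 and 0.54, n = 5 per group). Of the 37 lists, 15 were called by camera, 7 with a more positive effect in females and 8 with a more positive effect in males, and 0 with an estimated correlation. The 4 lists named here were called whichever of the 20 libraries was left out.

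No single gene passed the test of the difference (edgeR quasi-likelihood, 0 calls, smallest adjusted p = 0.587), while 1230 had an unadjusted p under 0.05 with 744 expected, and DESeq2 and limma voom with quality weights also called 0. The smallest p-values, none of which passed, were those of Mcm7 (0.59 ± 0.13), a subunit of the replicative helicase, with effects of 0.26 ± 0.09 in females and -0.33 ± 0.09 in males, Acbd4 (0.37 ± 0.09), Wnt16 (2.01 ± 0.50), Tbc1d10c (1.69 ± 0.43) and the retinol dehydrogenase gene Rdh10 (0.63 ± 0.16). In the other direction they were those of Elmod2 (-0.53 ± 0.12), Tmem200c (-0.64 ± 0.16), the fatty acid elongase gene Elovl6 (-0.58 ± 0.15), the purinergic receptor gene P2rx3 (-1.44 ± 0.37) and Gjc3 (-0.70 ± 0.17), a connexin gene of myelinating glia with effects of -0.31 ± 0.12 in females and 0.39 ± 0.12 in males. In simulated libraries, with genes drawn independently, this test recovered 34% of genes with a 1.5-fold and 65% of those with a 2-fold difference.

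Across the 14884 genes, which are not independent replicates, the stress effects in females and males had a Pearson r of -0.21 and a Spearman rho of -0.19, and 44.7% of genes had the same sign. There were 70 genes at an unadjusted p under 0.05 in both sexes, with 84 expected by chance, 40 of them with the same sign. The correlation rested on few libraries: it was 0.039 without susceptible male 5, 0.029 without susceptible female 5, -0.041 without female control 1, -0.11 without male control 4, -0.124 without susceptible female 2 and -0.322 without female control 5. With the region score as a covariate it was 0.074, and without the libraries with over 100 CPM of Ttr it was -0.048.

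**Figure D3:**
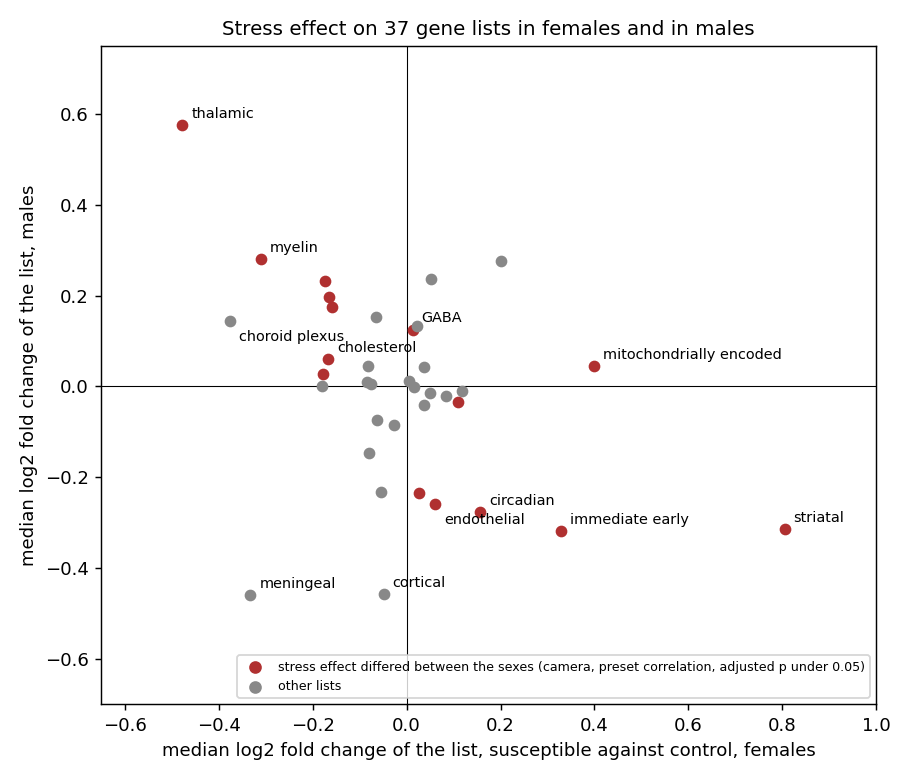
Median log2 fold change with stress of each of the 37 gene lists in females (horizontal axis) and in males (vertical axis), with the 15 lists that differed between the sexes by camera with a preset correlation in red. Striatal markers lay at 0.81 in females and -0.31 in males, and myelin markers at -0.31 and 0.28.

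Male and female controls were compared to describe the sex difference without stress. Among the genes higher in males, Pecam1, an endothelial adhesion gene, was 13.1 ± 1.13 CPM in females and 24.1 ± 4.27 CPM in males (log2 fold change 0.87 ± 0.14; chromosome 11, 106654217 to 106750628). The fibronectin gene Fn1 was 29.8 ± 5.87 and 64.2 ± 12.8 CPM (1.11 ± 0.21). Among the genes lower in males, Gjc3 was 123 ± 19.4 CPM in females and 77.9 ± 12.2 CPM in males (-0.66 ± 0.12) and Bcas1 was 223 ± 49.6 and 129 ± 34.8 CPM (-0.79 ± 0.17). In all, 76 genes passed (edgeR quasi-likelihood, adjusted p under 0.05), 43 higher and 33 lower in males, of which 5 lie on the Y chromosome, 3 on the X chromosome and 68 on autosomes. At an unadjusted p under 0.05 there were 2862 genes, with 744 expected. The split was 23 higher and 28 lower among the 51 genes called with GC and length offsets.

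Among the sex-linked genes, Ddx3y, Kdm5d, Eif2s3y and Uty were detected in every male control (edgeR adjusted p = 1.26e-15, 1.34e-11, 4.47e-11 and 4.98e-11). The X-linked Eif2s3x, a translation initiation factor gene that escapes X inactivation, was 101 ± 10.2 CPM in females and 64.0 ± 4.39 CPM in males (-0.66 ± 0.09, edgeR adjusted p = 0.00315; X chromosome, 94188707 to 94212862). X-linked escape genes were lower in males in 6 of 8 members (camera adjusted p = 0.000361, and 0.108 with an estimated correlation), and 4 passed when adjusted over the list alone.

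Among autosomal genes, the largest positive changes were those of the membrane transporter gene Slc4a11 (1.79 ± 0.33, edgeR adjusted p = 0.024), the leukocyte adhesion gene Icam1 (1.5 ± 0.32, 0.0459), the muscle transcription co-activator gene Mamstr (1.17 ± 0.23, 0.0354) and Vwf (1.13 ± 0.24, 0.0459), which was higher than the female mean in 4 of 5 male controls. The flow-induced transcription factor Klf2 (0.88 ± 0.19), the transglutaminase gene Tgm2 (0.74 ± 0.15), the NF-kB inhibitor Nfkbia (0.58 ± 0.10), the vascular surface gene Ly6c1 (0.52 ± 0.12) and Slc2a1 (0.42 ± 0.08; 71.7 ± 5.42 and 96.2 ± 2.18 CPM; chromosome 4, 119108711 to 119137983), the glucose transporter gene of the blood-brain barrier, were also higher (edgeR adjusted p = 0.0459, 0.0395, 0.0162, 0.0474 and 0.0322). Lower in males were the pituitary hormone genes Prl (-6.12 ± 1.30) and Gh (-5.46 ± 1.16), Meioc (-1.03 ± 0.21), the oligodendrocyte gene Ermn (-0.83 ± 0.18), the hyaluronan-binding gene Tnfaip6 (-0.68 ± 0.13) and the sterol oxidase gene Msmo1 (-0.44 ± 0.09), with edgeR adjusted p-values of 0.0462, 0.0459, 0.0403, 0.0464, 0.0319 and 0.0459. Prl and Gh were highest in female control 1, at 58.7 and 36.0 CPM, and at most 1.09 and 0.918 CPM in the male controls. Without female control 1 their log2 fold changes were -4.65 and -3.68. Male control 4 held the highest levels of both among male controls and was the only one with counts of Prl, so the size of its fold rests on that library.

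The number of calls between controls depended on single libraries. The number of genes called was 9 without female control 1, 14 without female control 2, 6 without female control 3, 13 without female control 4, 458 without female control 5, 193 without male control 1, 11 without male control 2, 25 without male control 3 and 23 without male control 5. The Y-linked genes and Eif2s3x passed in each of these. The call of Pecam1 was lost without female control 1 (0.86, edgeR adjusted p = 0.0511) or 3 (0.88, adjusted p = 0.053), where its log2 fold change stayed close to 0.87. That of Nfkbia was lost without the same libraries, at 0.57 and 0.55 against 0.58. Of the 24 named genes, 19 were lost without female control 1 (edgeR adjusted p of 0.0511 to 0.124) and without female control 3 (0.053 to 0.174). Leaving out female control 2 (0.0509 to 0.103), female control 4 (0.0538 to 0.0883) or male control 2 (0.0527 to 0.155) each ended 17 of the calls. Without male control 5, 14 were lost (0.062 to 0.0923), without male control 3, 12 (0.0654 to 0.0947), without male control 4, 4 (0.0636 to 0.0669) and without male control 1, 2 (both 0.0522). With the region score as a covariate 13 genes were called, 12 of them shared, and 5 were called without the libraries over 100 CPM of Ttr and also without those over 1 CPM of Pmch, with fewer libraries in each. The log2 fold change of Pecam1 was 0.89 and 0.92 in these, and that of Nfkbia 0.62 and 0.54, both without a call. Bcas1 went to -0.46 and -0.44, Gjc3 to -0.50 and -0.41 and Ermn to -0.56 and -0.57, so the difference in genes of myelinating glia was smaller there. Eif2s3x was -0.58 and lost its call without the libraries over 1 CPM of Pmch (edgeR adjusted p = 0.341). DESeq2 called 455 genes and limma voom with quality weights 3290.

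**Figure D4:**
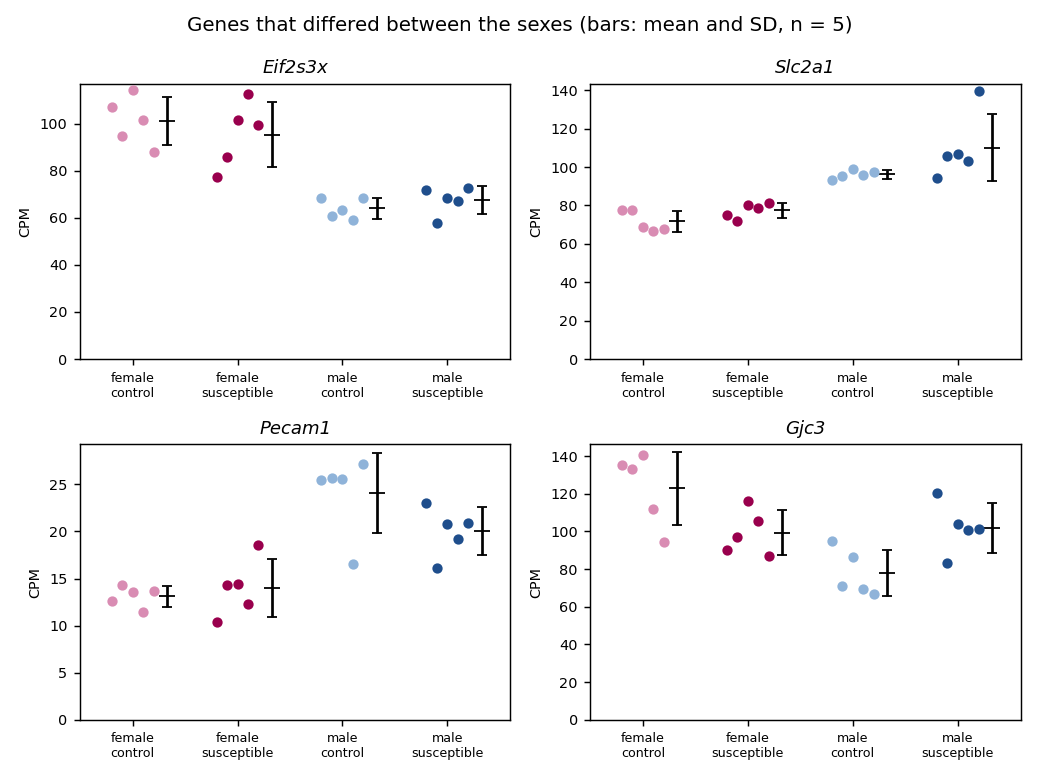
CPM of Eif2s3x, Slc2a1, Pecam1 and Gjc3 in each library by group, with the mean and SD of 5 libraries. Eif2s3x averaged 101 CPM in female controls and 64.0 CPM in male controls, and Pecam1 13.1 and 24.1 CPM.

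Gene groups differed between the controls in the same sense as these genes. Oligodendrocyte and myelin markers were lower in males in 26 of 26 members (median -0.62, camera adjusted p = 2.19e-16, and 0.362 with an estimated correlation), of which 1 passed over all genes and 22 when adjusted over the list alone. Mbp stood at -0.65 ± 0.15. Endothelial and pericyte markers were higher in 23 of 25 members (median 0.50, camera adjusted p = 1.12e-09, and 0.362 with an estimated correlation), 4 passing over all genes and 12 over the list alone. Glucocorticoid-responsive genes were higher in 27 of 30 members (median 0.44, camera adjusted p = 1.36e-06, and 0.387 with an estimated correlation), among them Fkbp5 (1.01 ± 0.28, edgeR adjusted p = 0.0908) and Sgk1 (0.46 ± 0.13, 0.106), with 3 passing over all genes and 8 over the list alone. Fkbp5 was 132 CPM in male control 5, 39.5 to 67.5 CPM in the other male controls and 28.1 to 36.1 CPM in female controls. The score of the list was 0.508 and 0.753 in male controls 4 and 5 and -0.097 to -0.082 in the other 3, so much of the difference rested on 2 libraries. Of the members that passed, Slc2a1 and Tgm2 are also expressed in vessel walls. Striatal markers were higher in 25 of 25 members (median 0.86, camera adjusted p = 6.74e-10, and 0.452 with an estimated correlation) and thalamic markers lower in 17 of 18 (median -1.22, camera adjusted p = 0.000619, and 0.56 with an estimated correlation). The region score, which is built from these 2 lists and so is no separate evidence, was 2.12 higher in males. Nuclear genes of oxidative phosphorylation were lower in 69 of 75 members (median -0.12, camera adjusted p = 5.39e-07, and 0.56 with an estimated correlation), a call that was lost with GC and length offsets (camera adjusted p = 0.0906). The thalamic call was lost without the libraries over 100 CPM of Ttr (0.0695) and without those over 1 CPM of Pmch (0.65).

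In total 15 lists were called between controls by camera, 0 with an estimated correlation and 5 by fry, which tests whether a list moves on balance in 1 direction. The fry calls included the myelin and endothelial lists (fry adjusted p = 0.0255 for both), while the glucocorticoid list stayed above the threshold (0.0563). With the region score as a covariate, camera still called the myelin (adjusted p = 5.49e-12), endothelial (3.19e-11) and glucocorticoid (7.06e-10) lists.

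Susceptible males and susceptible females were compared as the sex difference under stress. The 7 genes that passed (edgeR quasi-likelihood) were the 5 Y-linked genes Ddx3y, Kdm5d, Eif2s3y, Uty and Uba1y, the X-linked histone demethylase gene Kdm6a and Slc2a1. Kdm6a, which escapes X inactivation, was 51.4 ± 7.13 CPM in females and 34.7 ± 3.40 CPM in males (-0.57 ± 0.09, edgeR adjusted p = 0.00644; X chromosome, 18162575 to 18279936). Slc2a1 was 77.5 ± 3.94 CPM in females and 110 ± 17.4 CPM in males (0.51 ± 0.08, edgeR adjusted p = 0.0105) and was also among the calls between controls. Of the 7, 6 were higher and 1 lower in males, and 935 genes had an unadjusted p under 0.05 with 744 expected. DESeq2 called 15 genes and limma voom with quality weights 11. Leaving out susceptible female 4 gave 20 calls, and leaving out susceptible female 2 ended the call of Slc2a1 (0.48, edgeR adjusted p = 0.0514). With the replicate numbers as a block, 4 genes were called and Kdm6a (-0.57) and Slc2a1 (0.50) both had an adjusted p of 0.0558. A fit of the 2 groups alone also called 4 genes, and it left Kdm6a at -0.56 (edgeR adjusted p = 0.586) and Slc2a1 at 0.51 (0.593). Without the libraries over 100 CPM of Ttr there were 4 calls, with 4 libraries fewer. Kdm6a was then at -0.51 (edgeR adjusted p = 0.746) and Slc2a1 at 0.40 (0.421). Without those over 1 CPM of Pmch there were 13.

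Of the 71 genes called between controls that do not lie on the Y chromosome, 59 had the same sign between susceptible males and females. These genes are not independent, and the share over all tested genes was not computed, so this count does not show that the differences recur under stress. The 2 sets of calls shared 6 genes, of which 5 are Y-linked and were bound to be called in both, and 1 is Slc2a1. The difference between the 2 sex comparisons equals the interaction with its sign turned, which no gene passed (smallest edgeR adjusted p = 0.587).

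Among the gene lists between susceptible mice, X-linked escape genes were lower in males in 7 of 8 members (median -0.35, camera adjusted p = 7.32e-09, and 0.0018 with an estimated correlation), with Eif2s3x at -0.50 ± 0.09 and Ddx3x at -0.39 ± 0.08, and this was the 1 list of 37 that also held with an estimated correlation. Mitochondrially encoded genes were lower in males in 13 of 13 members (median -0.45, camera adjusted p = 7.47e-11, and 0.141 with an estimated correlation), of which 10 passed when adjusted over the list alone against 0 over all genes. The share of mitochondrial counts was 6.39% in susceptible females and 5.01% in susceptible males (exact permutation p = 0.0159, n = 5 and 5). Ribosomal protein genes were lower in males in 75 of 78 members (median -0.15, camera adjusted p = 1.28e-15, and 0.423 with an estimated correlation). These 3 lists were called by camera whichever library of the susceptible groups was left out, out of 18 lists called in this comparison.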

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

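The region score was chosen as a correction only after the differences between the controls had been seen, as were the corrections for GC content and exon length, and the tests of the dissection position on the calls between controls, of the autosomal calls over splits and of the fold changes of the male calls were written after those results had been seen.

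Between male and female controls 76 genes passed, 71 of them off the Y chromosome. Of 100 splits of the same 10 libraries, 3 gave as many calls, the real one included, with a highest other value of 1092. For the 68 autosomal calls 3 of 100 gave as many, with a highest other value of 1056. The count was thus larger than in most groupings of these libraries, with a share under 0.05. That share was not corrected for the other split tests, and the count depended on single libraries, so chance is not excluded. The split with 1092 calls set female controls 1 to 4 with male control 1 against the rest, had the largest difference in region score of the 100 (2.78, against 2.12 for the real split), and points to a structure of the samples. A GC and length trend as the whole cause is argued against, because the median absolute log2 fold change of the 71 genes kept 0.93 of its size with such offsets (95% interval 0.86 to 1.04 over genes, which are not independent), 0.54 ± 0.11 before and 0.50 ± 0.11 after, with 37 still called. Dissection position stays open: with the region score the ratio was 0.80 (0.71 to 0.95; 0.54 ± 0.11 and 0.43 ± 0.10, 7 still called), so dissection and an untested biological sex difference cannot be told apart here.

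Myelin markers were lower with stress in 26 of 26 members in females and higher in 25 of 26 in males, and 10 members passed the test of the difference when adjusted over the list alone. GC content and length are argued against, since the median difference kept 1.02 of its size (0.98 to 1.10) with such offsets. Dissection position may account for part of it: with the region score the median went from -0.62 to -0.40, a ratio of 0.65 (0.59 to 0.69), which met neither the bound set for a cause nor the bound set against one. The myelin score was 0.33 ± 0.35 in female and -0.33 ± 0.34 in male controls, but 0.01 ± 0.25 and 0.00 ± 0.19 in susceptible females and males. The pattern therefore cannot be told apart from a difference between the controls. A response of oligodendrocytes to stress that differs by sex stays open and was not tested otherwise.

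Between the male groups, limma voom with quality weights called 671 genes where edgeR called 0, and the Spearman correlation of the male log2 fold changes with GC content was -0.36 across genes. With the region score 358 genes were called, 300 of them among the 671 (a share of 0.45), and the median absolute log2 fold change of the 671 kept 0.91 of its size (0.89 to 0.93; 0.30 before and 0.27 after, with a median standard error of 0.07 in both). The region score itself differed by only -0.62 between the male groups (exact permutation p = 0.54), so this covariate could lower the fold changes little. It also leaves out other structures, such as the septal, preoptic and hypothalamic markers (score difference 0.52, exact permutation p = 0.0476, adjusted p = 0.315). The dissection position is therefore not decided by it. With the trend on GC content and exon length removed, 0 of the 671 passed, 524 still had an unadjusted p under 0.05, and the median kept 0.62 of its size (0.60 to 0.65; 0.30 ± 0.072 before and 0.18 ± 0.065 after). Both shares met the bound for a cause set before the data on them were seen (0.5 or fewer of the calls left), but calls can be lost at the threshold while fold changes stay, so the fold changes were used, which for the trend met neither bound and leave it as one that may account for part of the calls. The dissection position stays open, and a biological effect of stress in males stays open and untested.

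A further 14 gene lists differed between the sexes in their response to stress by camera with the preset correlation, beside the myelin list (adjusted p = 1.45e-14). They were striatal markers (2.99e-10), immediate early genes (4.02e-08), ribosomal protein genes (5.92e-06), circadian clock genes (5.92e-06), cholesterol synthesis genes (0.000149), oligodendrocyte precursor markers (0.000376), mitochondrially encoded genes (0.00216), astrocyte markers (0.00273), endothelial and pericyte markers (0.00512), thalamic markers (0.0133), GABA signalling genes (0.0223), sex steroid genes (0.0311), the CRH, vasopressin, oxytocin and PACAP system (0.0325), and interferon and antigen presentation genes (0.0357). None held with an estimated correlation (smallest camera adjusted p = 0.378). The ribosomal list lost its call without susceptible female 1 (adjusted p = 0.121) and the GABA list without female control 4 (0.064) or male control 5 (0.0843). The thalamic list lost its call without female control 1 or 2, susceptible female 1, 2 or 5, or susceptible male 5 (0.0507 to 0.213), and the CRH list without female control 1 or 5, male control 2 or 5, susceptible female 3 or 5, or susceptible male 2 (0.0517 to 0.0765). The sex steroid list lost it without female control 4 or 5, male control 2, 4 or 5, susceptible female 1 or 5, or susceptible male 1 or 2 (0.0504 to 0.0939). The interferon list lost it without female control 1, 4 or 5, male control 2 or 4, susceptible female 3 or 4, or susceptible male 1, 2 or 5 (0.057 to 0.17). With the region score the mitochondrial list lost its call (0.0813) and the thalamic list passed in the opposite direction (0.00867), the score being built in part from that list. Without the libraries over 1 CPM of Pmch the thalamic list also did so (0.0166), and the mitochondrial (0.183), astrocyte (0.391) and CRH (0.0564) lists lost their calls. Without those over 100 CPM of Ttr the cholesterol (0.078), CRH (0.215), sex steroid (0.238) and thalamic (0.491) lists lost theirs. Chance cannot be excluded for the 15 lists: 10 of 100 splits called as many, with a highest other value of 21 and a median of 10 lists in the other splits.

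Single libraries lay apart from the other 4 of their group, by the gap to the nearest library over the range of the group, in 31 of 302 groups of values, where about 15 would be expected at 1 in 20. That number is only a rough guide, because many values are skewed CPM and some depend on each other, such as the thalamic score and the region score. The excess therefore does not show that these libraries are faulty. Female control 1 had the highest Prl (58.7 CPM, others 0.730 to 12.6) and Gh (36.0 CPM, others 0.862 to 4.44), the lowest Icam1 (1.59 CPM) and the lowest microglia score (-0.43). Other female controls stood apart for P2rx3 (control 2, 2.36 CPM), Meioc (control 4, 2.03 CPM) and Fos (control 5, 52.7 CPM, others 29.1 to 33.6).

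Male control 1 was highest for Esr1 (11.2 CPM), Msmo1 (79.1 CPM), thalamic markers (score 0.664) and septal, preoptic and hypothalamic markers (0.498). Male control 4 was lowest for Pecam1 (16.5 CPM, others 25.5 to 27.1) and highest for Mc4r (6.37 CPM), Gh (0.918 CPM) and Prl (1.09 CPM, others 0). Male control 5 was highest for Wnt16 (1.87 CPM) and lowest for the microglia (-0.641) and blood cell (-2.70, others 0.278 to 0.725) scores.

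Susceptible female 4 was highest for Esr1 (21.9 CPM, others 3.17 to 5.47), 4933402D24Rik (1.73 CPM) and Nyap1 (94.7 CPM), and susceptible female 5 was highest for Tbc1d10c (3.25 CPM) and Epha2 (3.10 CPM) and lowest for the astrocyte score (-0.354). Susceptible male 4 was highest for Kdm5d (60.4 CPM). Susceptible male 5, with 6 such values the most of any library, was highest for Slc2a1 (140 CPM), Ccnc (40.6 CPM), Prkcd (350 CPM, others 19.2 to 110.9), thalamic markers (1.62, others -0.723 to -0.552) and astrocyte markers (0.124), and had the lowest region score (-2.52, others 0.392 to 1.30).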

How the results depend on the processing

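Alternatives chosen only after the data were seen were those without libraries high in Ttr or Pmch, with the region score, with GC and length offsets, and the voom fits that add the GC trend or the region score. The other settings given in this part were fixed before. For the counts of calls and the correlation, 211 values kept their side of the threshold or stayed within 1.5 times, 26 were lower and 14 higher by more than that, and 4 correlations moved and 3 turned sign. For named genes 2218 kept direction and side of the threshold while 235 no longer passed, 28 passed anew and 119 changed sign.

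Counts of calls moved as follows, and the cause was not tested unless a value or the setting shows it. With the DESeq2 Wald test 24 genes were called in males, 29 on average, 455 between controls and 15 between susceptible mice. With voom quality weights the counts were 671 in males, 3290 between controls and 11 between susceptible mice, and with the GC and length trend removed as well 0 in males and 3031 between controls. Quality weights with the region score left 358 in males. Between controls, 38 genes were called without a count filter (18949 genes tested), 13 with 1 surrogate variable, 13 with the region score, 19 with the 2 groups alone, and 5 without libraries high in Ttr and also without those high in Pmch, with fewer libraries. Between susceptible mice, the counts were 4 with the 2 groups alone, 4 without libraries high in Ttr and 13 without those high in Pmch. Called lists fell to 0 with an estimated correlation in females, males, their difference and controls, to 0 with fry in the first 3 and 5 between controls, and to 10 in females without libraries high in Pmch. The correlation of female and male effects became 0.074 with the region score and -0.048 without libraries high in Ttr.

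The replicate numbers did not pair the libraries. Correlations of deviations between libraries with the same number ran from -0.45 to 0.70 for stress in females, 0.00 to 0.26 in males, -0.15 to 0.55 between controls and -0.42 to 0.15 between susceptible mice, and at most 2 of 5 libraries correlated best with their own number. With the replicate block, 0 genes were called for stress, 110 between controls (60 shared) and 4 between susceptible mice.

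Leaving out 1 library at a time gave 0 to 2 calls in females (2 without susceptible female 4), 6 to 458 between controls (458 without female control 5, 6 without female control 3), 6 to 20 between susceptible mice (20 without susceptible female 4), 10 to 16 lists in females (10 without susceptible female 1) and a correlation of -0.322 to 0.039. None of the named genes that changed sign had passed in any stress comparison. Their log2 fold changes with 1 library left out ranged in females from -0.07 to 0.45 for Npy, -0.61 to 0.04 for Crhbp, 0.00 to 0.18 for Fkbp5, -0.16 to 0.29 for Crhr2, -0.22 to 0.58 for Cartpt, -0.11 to 0.04 for Sst, -0.65 to 0.15 for Prkcd, -0.58 to 0.33 for Tac2 and -0.24 to 0.23 for Mc4r. In males they ranged from -0.42 to 0.94 for Prkcd, -0.40 to 0.16 for Fkbp5, -0.12 to 0.04 for Crhr1, -0.07 to 0.40 for Bdnf, -0.03 to 0.05 for Adcyap1r1, -0.18 to 0.63 for Cyp19a1, -0.02 to 0.04 for Nr3c1 and -0.10 to 0.08 for Oxtr.

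Other settings turned the sign in females as follows, all causes untested. With the region score Adcyap1 was 0.08, Npy -0.16, Cartpt -0.10 and Prkcd 0.57. With 1 surrogate variable Npy was -0.12, Cartpt -0.04 and Prkcd 0.43. With quality weights Sst was 0.03, Tac2 -0.26 and Mc4r -0.13, with the replicate block Tac2 -0.18 and Mc4r -0.04, and with GC offsets Mc4r -0.03. Without libraries high in Ttr Nts was -0.01, Nr3c1 0.01, Crhr2 -0.46, Cartpt -0.47, Tac2 -0.54 and Mc4r -0.21. Without those high in Pmch Pdyn was -0.10, Nts -0.28, Crh -0.19, Nr3c1 0.05, Npy -0.23, Cartpt -0.24, Prkcd 0.84, Tac2 -0.12 and Mc4r -0.41.

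In males the signs turned with 1 surrogate variable for Prkcd (-0.17), Penk (0.10), Crhr1 (0.02), Adcyap1r1 (-0.02), Nr3c1 (-0.03) and Oxtr (0.12), and with the region score for Prkcd (-0.17), Penk (0.02), Adcyap1r1 (0.00), Nr3c1 (-0.02) and Oxtr (0.08). Without libraries high in Ttr they turned for Prkcd (-0.35), Adcyap1 (0.00), Crhr2 (-0.02), Fos (0.12), Bdnf (-0.13) and Oxtr (0.09), and without those high in Pmch for Prkcd (-0.41), Penk (0.01), Crhr1 (0.05), Bdnf (-0.06), Nr3c1 (-0.01) and Oxtr (0.06). GC offsets turned Crhr1 (0.04), Nr3c1 (-0.06) and Oxtr (0.05). Quality weights turned Prkcd (-0.15), Fkbp5 (0.07) and Oxtr (0.07), with the GC trend removed Prkcd (-0.06), Fkbp5 (0.15), Crhr1 (0.01), Nr3c1 (-0.07) and Oxtr (0.15), and with the region score Prkcd (-0.25), Fkbp5 (0.14), Penk (0.03), Adcyap1r1 (-0.02), Nr3c1 (-0.02) and Oxtr (0.16). The block turned Cyp19a1 (-0.03) and Oxtr (0.00), and Oxtr, whose main value was 0.00, turned within rounding with DESeq2 size factors (0.00), the DESeq2 Wald test (0.00), the stricter filter (0.01) and the 2 groups alone (0.00).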

Other observations

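The tests of Sgk1 against the oligodendrocyte share and of the clock genes against collection time were chosen after the results for Sgk1 and the circadian list had been seen, and so was the test of the autosomal calls between susceptible mice over splits.

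Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, varied in female controls from 143 CPM in female control 5 to 388 CPM in female control 2, while susceptible females spanned 100 to 137 CPM. Hcrt, the orexin precursor of the lateral hypothalamus, was 82.5 CPM in female control 1, 28.7 in female control 2, 12.2 in susceptible male 5, 4.91 in female control 3 and 4.34 in susceptible female 4, the same 5 libraries that had over 1 CPM of Pmch.

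The stress effect on Sgk1 was 0.48 ± 0.13 in females and 0.49 ± 0.13 in males, and oligodendrocytes are a known site of its induction by glucocorticoids. A hypothesis is that a larger share of oligodendrocyte RNA raised it. With the myelin score as a covariate the average effect kept 0.99 of its size (0.48 ± 0.09). This cannot decide the question, because the score moved by -0.32 in females and 0.33 in males, which nearly cancel in the average. By sex, the effect with the covariate was 0.53 ± 0.14 in females and 0.43 ± 0.14 in males. Myelin markers were lower with stress in females, the opposite of what the hypothesis needs there, and in males it stays open. Whether the response is one of glucocorticoid signalling stays an open hypothesis. The glucocorticoid list, which holds Sgk1, was higher with stress in 22 of 30 members in females (median 0.12, camera adjusted p = 0.0206, and 0.699 with an estimated correlation), a call lost without female control 3 (0.0599), female control 4 (0.0766) or susceptible female 1 (0.114), and without the libraries over 100 CPM of Ttr (0.481). In males 15 of 30 members were higher (median -0.01, camera adjusted p = 0.378), and the effects in the sexes were not shown to differ (0.484).

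A difference in collection time between the groups is a candidate explanation for the circadian list. It predicts that the genes of the Per, Dbp and Nr1d arm move against those of the Arntl and Clock arm. The Arntl and Clock arm also held Npas2 and Nfil3. Between male groups the arms differed by -0.24 ± 0.07 and -0.07 ± 0.07 and the phase score did not separate the groups (exact permutation p = 0.119, n = 5 and 5). Within the Arntl and Clock arm, Arntl (0.14 ± 0.14) and Clock (0.07 ± 0.09) had positive estimates there. Those of Npas2 (-0.40 ± 0.27) and Nfil3 (-0.06 ± 0.16) were negative. Between female groups the arms differed by 0.20 ± 0.10 and 0.15 ± 0.13, also in the same direction (exact permutation p = 0.635 for the phase score, n = 5 and 5). The second value rested on Npas2 (0.54 ± 0.27). Arntl (0.10 ± 0.14), Clock (-0.01 ± 0.09) and Nfil3 (0.03 ± 0.16) lay within 1 standard error of 0, so collection time is not decided there. Between controls the arms differed by 0.35 ± 0.08 and 0.10 ± 0.08 on average, with an exact permutation p of 0.0238 for the phase score (n = 5 and 5; adjusted p = 0.0952 over 4 comparisons). The positive mean of the Arntl and Clock arm rested on Npas2 (0.84 ± 0.27). Arntl (-0.22 ± 0.14), Clock (-0.08 ± 0.09) and Nfil3 (-0.20 ± 0.16) were lower in males, against the Per arm, the direction that collection time predicts. The bound set against collection time, both arms in the same direction by more than 1 standard error, was met between controls, but only through Npas2. The Arntl and Clock arm passed it by less than its own standard error, and a bound of 2 standard errors, adopted after that outcome was seen, was not met. Collection time therefore stays open between the male groups, between the female groups and between controls.

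Other splits of the same libraries were compared with the real ones. For the 7 calls between susceptible mice 1 of 100 splits gave as many (highest other 6), but 6 of the 7 are sex-linked genes, for which the real split was bound to differ, so this decides nothing. For the 1 autosomal call, Slc2a1, 4 of 100 splits gave as many (highest other 6) in the fit to all 20 libraries. This share is narrowly under 0.05 and was not corrected for the other split tests, so chance is not excluded. The call of Slc2a1 was lost without susceptible female 2 (0.48, edgeR adjusted p = 0.0514), with the replicate block (0.50, 0.0558), with the 2 groups alone (0.51, 0.593) and without the libraries over 100 CPM of Ttr (0.40, 0.421). For the 16 lists called in females with the preset correlation, 2 of 100 splits called as many (highest other 17, median 11). This share is under 0.05 but was not corrected for the other split tests, so chance is not excluded for the count. That count was 10 without susceptible female 1, and 0 with an estimated correlation (smallest adjusted p = 0.411) or fry (0.223). Chance cannot be excluded for the 15 lists called in males (17 of 100, highest other 20, median 10), the 15 lists called between controls (8 of 100, highest other 17, median 11) or the correlation of -0.21 between female and male effects (50 of 100, farthest other 0.67). With 0 real calls, all 100 splits gave as many for stress in females (highest other 3091), in males (4), on average (1088) and for the difference between the sexes (3709). The female split with 3091 calls set female controls 1 to 3 with susceptible females 3 and 4, and had the largest difference in region score of the 100 splits (3.23, against 1.48 for the real split), which points to a structure of the samples other than stress.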
